A study of Mus musculus with 9 samples.

How the data were processed

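Total RNA of the whole left kidney was measured in 9 male mice aged 10 weeks. The mice belong to the ISAM line, a model of erythropoietin-deficiency anaemia on a mixed strain background. Per the labels, 500 ng of RNA per kidney was amplified, labelled with Cy3 and hybridized to a single-colour Agilent mouse array. Per the file headers the array is design 014868, read on a G2505C scanner with Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09, and the grid names build mm9. No coordinates were used.

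The deposited scanner files give each spot as an intensity. Per the file headers, Feature Extraction subtracted the background and removed spatial trends within each array. No scaling between arrays had been applied. The deposited files also hold other columns, with flags of 0 or 1 for spots well above background, saturated spots and outlier spots. A deposited table of log2 values covers all 9 arrays. It holds 41267 rows, of which 8142 carry values. Of these, 8107 lay within 0.02 (root mean square over the 9 arrays, row means removed) of the scanner values of a probe other than the one the row names, and 0 lay that close to their own probe. The median correlation over the 9 arrays with the row's own probe was 0.0177. The names and values of that table do not belong together, so it was not used.

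Each array held 45018 spots, of which 1639 were control spots, and 41174 distinct probes. Intensities were divided by the array's 75th percentile and taken to log2, so that a level of 0 is the 75th percentile. Repeated spots were averaged without spots carrying an outlier flag. Probe accessions were matched to gene symbols through the RefSeq table: 26690 probes had a symbol and 14484 kept only their accession. A probe was kept when it was well above background on at least 3 of the 9 arrays, which 23565 were; 21 of these were left out for an outlier flag on every spot of an array. The brightest probe stood for each gene, which left 17742 genes, 13017 with a symbol and 4725 with an accession alone. No spot was saturated. The share of probes well above background was 52.0% to 57.5% per array.

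The labels give 4 groups: sham (2 arrays), untreated (1), clip (3) and release (3). Sham and untreated arrays formed the control arm of 3, a choice made, like the comparisons, lists, naming rule and most alternatives, before the data were examined. Linear models with moderated variances were fitted with limma 3.58.1 in R 4.3.3, with 3 arms over all 9 arrays. P values were adjusted by the Benjamini-Hochberg (BH) method within each comparison, with 0.05 as the threshold. The prior had 2.37 degrees of freedom. Errors are standard errors from the fit, which pools the spread of the arms, and each arm has n = 3 unless stated.

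There were 38 lists of genes, for nephron segments, other cell types and pathways. Each was tested with camera at a preset correlation of 0.01 between genes, BH-adjusted over the 38 lists within a comparison, and again with a correlation estimated from the residuals. Counts of changed members are given both with adjustment over all genes and adjusted over the list alone. The named genes were fixed by rule. They are the 10 largest rises and 10 largest falls in each comparison among symbols past the threshold whose arms do not overlap and whose probe is above background throughout the brighter arm. Added to these are, per list, the 2 largest rises and 2 largest falls past the threshold, or the 2 smallest p values where fewer than 2 passed. A fixed set of genes is named throughout: Epo, Acta2, Col1a1, Col3a1, Tgfb1, Ccl2, Havcr1, Lcn2, Pdgfrb, Umod, Slc34a1 and Kap. Where no array of the dimmer arm was well above background, the change is given as "at least" a fold. The dimmer level on each array was the gene's own signal, or the lowest signal of any probe well above background where that was higher. Such a bound is not strict, and normexp gave smaller changes for several of these genes.

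Each of the 3 slides carried 1 array of each arm, and slide 3, with the untreated array, was scanned on another of the 2 scan dates. Deviations from the arm means correlated across genes at 0.161 to 0.282 between the 9 pairs of arrays on the same slide. Between the 18 pairs of arrays of different arms on different slides they correlated at -0.239 to 0.00291. Pairs of the same arm, whose deviations are taken from a shared mean, are left out. A fit with slide as a block was therefore run beside the counts, the lists and the named genes. The replicate numbers of the clip and release arrays follow the slides, so a fit with the replicate number as a block was also run. The untreated array has number 1 but lay on slide 3, so this block joins it with arrays of another slide. Its deviations correlated at -0.209 with both clip 1 and release 1. With clip 3 and release 3, on its own slide, they correlated at 0.282 and 0.279. Calls lost with the replicate block may in part come from this placing.

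The alternatives were normexp background correction (offset 50, on median spot and background pixels, since the files hold no mean), quantile normalization, other filters and probe choices, other models, sham arrays alone as the control, blocks, and each array left out in turn. The pipeline was tested on simulated data for 17742 genes with 200 changed. In clip minus control it recovered 28.4% of the 1.5-fold changes, 76.1% of the 2-fold and 92.4% of the 4-fold. In release minus control the shares were 25.4%, 58.2% and 92.4%. In release minus clip they were 20.9%, 65.7% and 95.5%. The false share of the calls was 1.50%, 4.88% and 5.47% in the 3 comparisons. In a simulation with 38 lists of 30 genes, the 1 raised list was called and 0 of the others. In both simulations the genes were drawn independently and without a slide effect. Some real lists were correlated, the proximal tubule list at an estimated 0.404. The simulation therefore does not show how often camera at the preset correlation calls unchanged lists of correlated genes. Figures and table checks used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.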

Results

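Reversible obstruction of the left ureter was studied in anaemic ISAM mice, which make too little erythropoietin. A clip closed the left ureter for 2 days. Kidneys were taken at the end of this time (clip, 3 mice) or 12 days after the clip had been removed (release, 3 mice). The control arm of 3 mice joined 2 sham-treated mice and 1 untreated mouse. The labels give no day of collection for these mice, so they are not known to match either other arm in time after surgery. Effects of surgery and elapsed time may therefore be part of both comparisons with control. The 75th percentile of the signal ran from 320 to 439 over the 9 arrays, and the share of probes well above background from 52.0% to 57.5%. Across genes, arrays of the same arm correlated at 0.979 to 0.990, clip with control arrays at 0.923 to 0.938, and release with control arrays at 0.977 to 0.986. Genes are not independent replicates in these correlations. The first principal component held 66.6% of the variance and set the clip arrays (74.4 to 85.1) apart from control (-50.3 to -49.0) and release arrays (-31.1 to -27.3). Within the control arm the single untreated array, which has no spread of its own, was set against the 2 sham arrays. It lay on another slide, scanned on another date, so slide and scan differences are part of this comparison unless slide is a block. Of 17742 genes 93 passed (limma, BH-adjusted; 45 higher and 48 lower in the untreated kidney; 2176 at an unadjusted p under 0.05), against 31 with slide as a block and 0 with normexp background correction (574 unadjusted). Neither probe for Epo was well above background on any array, so no change of this gene is given.

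The first comparison asked what 2 days of obstruction changed in the kidney. Genes of injured tubule epithelium rose, and most genes of the thick limb and distal tubule fell (for both lists, camera adjusted p = 0.061 with an estimated correlation). Havcr1, which encodes the injury marker KIM-1, rose 734-fold (log2 change 9.52 ± 0.36, n = 3 per arm; limma, BH-adjusted p = 1.23e-06; 7.31 with normexp background correction), from a control level well above background on 1 of 3 arrays. Lcn2, for the secreted injury protein NGAL, rose 117-fold (6.87 ± 0.38; 4.61 with normexp; 2 of 3 control arrays well above background). Egf, a product of the thick ascending limb and distal convoluted tubule, fell 125-fold (-6.97 ± 0.10, adjusted p = 1.91e-08). The collagen, chemokine, macrophage and cell cycle lists rose, and the fatty acid oxidation and respiratory chain lists fell, at the preset correlation of camera; adjusted p = 0.0907, 0.0827, 0.0615, 0.061, 0.186 and 0.19 with an estimated correlation.

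Of the 17742 genes, 3789 were higher and 4887 lower in clip than in control kidneys (limma, BH-adjusted), which is 48.9% of those tested. Changes of 2-fold or more made up 1674 of the rises and 1684 of the falls. The arms did not overlap in 8568 of the 8676 called genes and in 58.6% of all genes, where chance gives 10%. On every slide the change had the same direction in 8655 of the called genes. With quantile normalization the larger side changed, with 4353 genes higher and 4210 lower. With normexp background correction 2519 were higher and 3107 lower, and 758 of the 8676 called genes had the other sign. The median change of all genes was -0.09 on the log2 scale, against -0.02 with quantile normalization and 0.10 with normexp.

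By the fitted change (log2 9.53) the rise of Sprr2f, a cornified-envelope protein, was as large as that of Havcr1. It rose at least 192-fold from a control level not well above background. This bound lies below the 450-fold rise of Fgb, so the rank of Sprr2f is not firm. The fibrinogen chains Fgb and Fgg rose 450-fold (8.81 ± 0.28) and 84.3-fold (6.40 ± 0.17). Saa2, Serpina10 and Meltf, also not well above background in control kidneys, rose at least 41.6-fold, 37.2-fold and 27.2-fold. Timp1 rose 158-fold (7.30 ± 0.34) and complement C3 82.1-fold (6.36 ± 0.30). Besides Egf, the largest falls included the distal convoluted tubule genes Pvalb, which fell at least 17.8-fold, and Tmem207, both to levels not well above background. The carboxylesterases Ces1g (-4.98 ± 0.52) and Ces1e (-4.80 ± 0.20), the tyrosine-degrading enzyme Hpd (-4.84 ± 0.30) and Gpx6 (-4.71 ± 0.21) fell 26.2-fold to 31.6-fold. Angptl7 fell 24.9-fold (-4.64 ± 0.95), and Sox2ot and Odf4 at least 16.6-fold and 9.95-fold; the call of Odf4 was not kept with normexp (adjusted p = 0.11). Normexp also gave smaller log2 changes for genes that are dim in 1 arm, below the bounds given here: 5.35 for Sprr2f, 3.37 for Serpina10, 2.78 for Meltf, -1.62 for Pvalb and -1.37 for Sox2ot. Fgb, and among the genes named below Trpv5, Inhba and Chil3, were well above background on 2 of 3 control arrays.

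**Figure D1:**
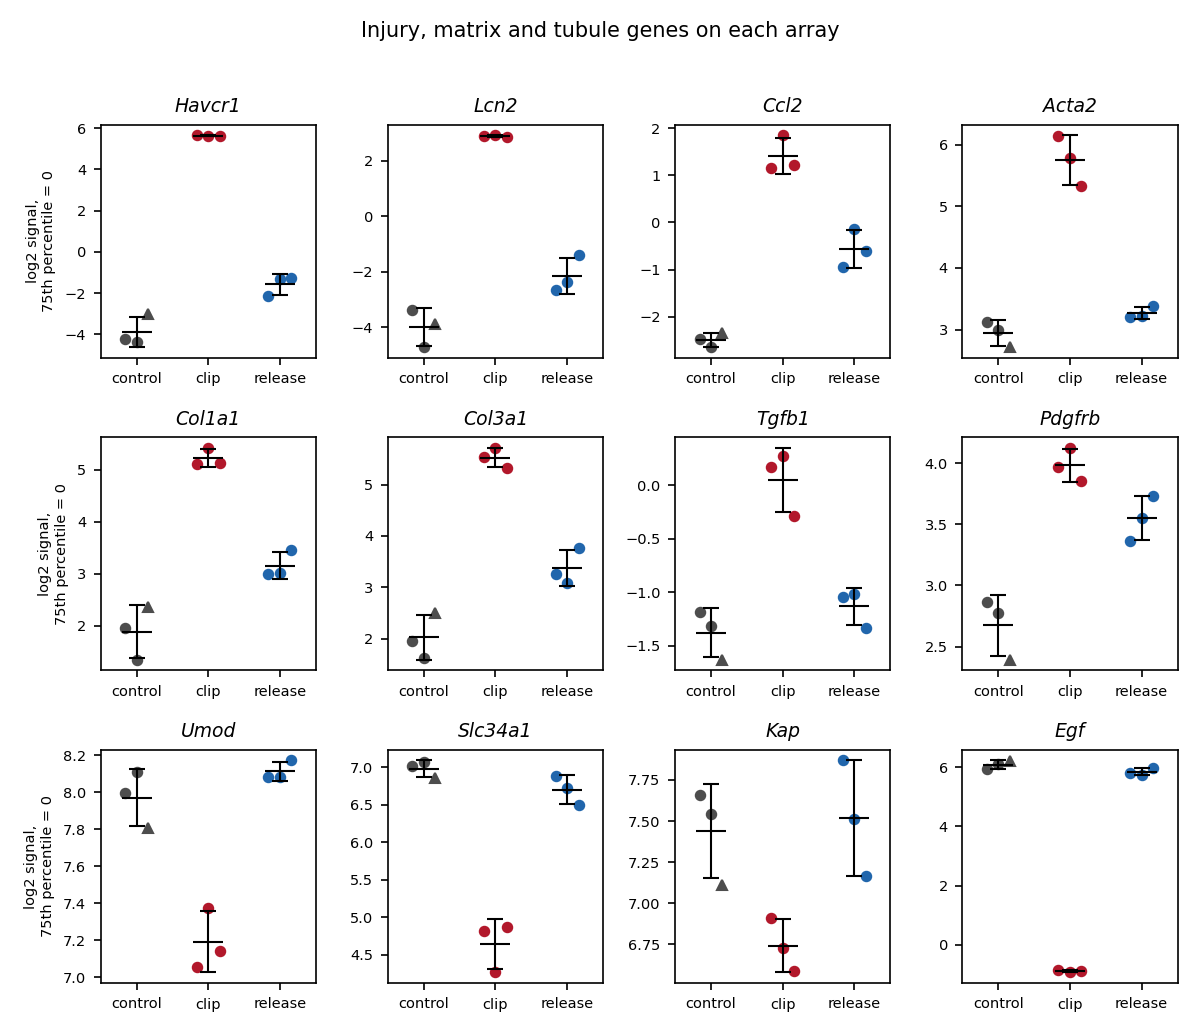
Log2 signal, scaled so that the 75th percentile of each array is 0, of 12 genes on each of the 9 arrays, with the mean and SD of each arm as bars; the triangle marks the untreated kidney. Havcr1, Lcn2, Ccl2 and the collagens lie highest in the clip arm, and Egf lies lowest there (log2 change -6.97).

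In the proximal tubule list 28 of 31 tested members fell, 1 rose and 2 did not pass (29 fell and 1 rose adjusted over the list alone), with a median change of -1.56 (camera, adjusted p = 4.44e-10; adjusted p = 0.186 with an estimated correlation). Among them were the phosphate carrier Slc34a1 (-2.33 ± 0.18), Slc7a13 (-3.94 ± 0.23) and the organic anion transporter Slc22a8 (-3.56 ± 0.42), while the sulfate carrier Slc13a1 rose 2.32-fold. In the thick limb and distal tubule list 18 of 20 fell and 1 rose, by either adjustment (median -1.62, adjusted p = 3.33e-08; adjusted p = 0.061 with an estimated correlation). Umod, the most abundant thick limb product, fell only 1.72-fold (-0.78 ± 0.12), and the calcium channel Trpv5 rose 3.31-fold. In the intercalated cell list 13 of 15 genes fell, the anion exchanger Slc4a1 by 21.1-fold (median -1.64, adjusted p = 7.95e-06; adjusted p = 0.186 with an estimated correlation). In the collecting duct principal cell list 5 genes fell, among them the water channels Aqp2 (-1.77 ± 0.17) and Aqp3 (-2.56 ± 0.16), 2 rose and 5 did not pass, and the list did not pass (adjusted p = 0.0992). Kap, an androgen-regulated proximal tubule gene, fell 1.62-fold (adjusted p = 0.0216), a call not kept with quantile normalization (adjusted p = 0.14), with replicate as a block (0.0568), or without sham 1 (0.07), sham 2 (0.0654), clip 2 (0.0591) or clip 3 (0.0673).

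Most genes of the energy metabolism lists fell with the tubule genes. In the respiratory chain list 29 of 31 members fell and none rose (30 adjusted over the list alone; median -0.89, adjusted p = 5e-10; adjusted p = 0.19 with an estimated correlation), with Sdha at -1.59 ± 0.11 and Ndufs1 at -1.47 ± 0.13. In the fatty acid oxidation list 25 of 30 fell (27 adjusted over the list alone; median -1.36), in the gluconeogenesis and amino acid list 22 of 25 (median -1.86) and in the xenobiotic and steroid list 26 of 28 (median -1.64), with the last counts the same adjusted over the list alone. Their camera values were 9.32e-10, 7.84e-08 and 3.04e-09, against adjusted p = 0.186, 0.186 and 0.143 with an estimated correlation. Acsm2 fell 5.96-fold, the glucose-6-phosphatase gene G6pc 12.8-fold and Cyp2d9 11.1-fold. Hypoxia and HIF targets were lower as a list (17 of 25 fell, 3 rose; median -0.43, adjusted p = 0.0016; adjusted p = 0.0723 with an estimated correlation): Car9 fell 7.23-fold and Vegfa 2.68-fold, while the hexokinase Hk2 rose 5.83-fold. The renin-angiotensin, klotho and vitamin D list was lower (8 of 12 fell; adjusted p = 0.0201; adjusted p = 0.186 with an estimated correlation), with Kl down 4.35-fold; this list was lost with replicate as a block (adjusted p = 0.0605).

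Most genes of the injury, proliferation and inflammation lists rose together. All but 1 of the 23 tubular injury genes rose, the exception being Hbegf, which fell 2.23-fold (median 2.28, adjusted p = 1.77e-14; adjusted p = 0.061 with an estimated correlation). In the cell cycle list 29 of 31 rose and 2 did not pass (median 2.70, adjusted p = 3.13e-17; adjusted p = 0.061 with an estimated correlation): Uhrf1 rose 16.4-fold (4.04 ± 0.15), and Ccnb1 rose from a level not well above background. In the macrophage and monocyte list 22 of 23 rose (median 2.13, adjusted p = 2.75e-13; adjusted p = 0.0615 with an estimated correlation), with Chil3 up 25.9-fold (4.70 ± 0.61) and the monocyte receptor Ccr2 at least 3.91-fold. In the chemokine list 16 of 21 genes rose and 1 fell (16 and 2 adjusted over the list alone; adjusted p = 5.38e-08; adjusted p = 0.0827 with an estimated correlation). Ccl2 rose 14.9-fold, Ccl20 at least 11.5-fold and Ccl12 at least 18.3-fold, whereas Cxcl12 fell 3.59-fold. The NF-kappaB list (18 of 21 rose, Vcam1 by 9.41-fold and Il6 at least 3.05-fold) and the interferon list (21 of 23 rose, Gbp2 by 5.24-fold) were higher too, with adjusted p of 1.29e-09 and 9.32e-10; adjusted p = 0.0972 and 0.0907 with an estimated correlation.

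In the collagen and matrix list 24 of 29 rose and none fell (25 rose and 1 fell adjusted over the list alone; median 1.36, adjusted p = 2.71e-11; adjusted p = 0.0907 with an estimated correlation). Col3a1 rose 11.3-fold and Col1a1 10.1-fold (3.33 ± 0.25). The myofibroblast list (13 of 16 rose; adjusted p = 5.38e-08; adjusted p = 0.186 with an estimated correlation) included Acta2, the smooth muscle actin of myofibroblasts, at 6.96-fold (2.80 ± 0.20) and S100a4 at 4.96-fold. The size of the Acta2 rise depended on the probe. Levels of the brightest, used here, were 2.72 to 3.13 in control and 5.33 to 6.13 in clip kidneys. A dim Acta2 probe gave -2.99 to -2.67 and -0.46 to 0.34. Another, above background on all 9 arrays, moved less, with 2.18 to 2.64 and 3.02 to 3.46. In the interstitial fibroblast and pericyte list 8 of 16 rose and 2 fell (adjusted p = 0.0057; adjusted p = 0.186 with an estimated correlation): Thy1 rose 7.10-fold and Pdgfrb 2.47-fold, and the pericyte gene Rgs5 fell 1.93-fold. Matrix proteases and inhibitors (11 of 21 rose and 2 fell, 12 and 2 adjusted over the list alone, Mmp7 at least 19.6-fold; adjusted p = 0.000765) and TGF-beta signalling (14 of 26 rose and 2 fell, 14 and 3 adjusted over the list alone, Inhba by 6.89-fold and Tgfb1 by 2.69-fold; adjusted p = 0.00883) passed, with adjusted p = 0.146 and 0.22 with an estimated correlation. Bmp7, of the last list, fell 2.31-fold.

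Complement, MHC class II, T and NK cell, and p53 and cell death lists were also higher, with camera adjusted p of 0.0057, 0.000693, 0.00299 and 0.026; adjusted p = 0.0907, 0.254, 0.383 and 0.186 with an estimated correlation. The p53 list was lost with normexp (mean 0.24 in place of 0.47, adjusted p = 0.293) and with replicate as a block (adjusted p = 0.0705). Complement members passed in 7 of 15 cases as rises and 2 as falls (8 and 2 adjusted over the list alone), MHC class II in 6 of 9 as rises (7 adjusted over the list alone), T and NK cells in 8 of 13, and p53 genes in 9 of 21 with 3 falls. Cfi rose by 3.42 ± 0.20 on the log2 scale, H2-DMa 4.58-fold, Cd5 3.27-fold, and the death genes Ripk3 and Bbc3 6.35-fold and 4.38-fold. The podocyte, endothelium, neutrophil, B cell and plasma cell, NRF2 target, iron handling, erythroid cell, urothelium, adipocyte, adrenal, skeletal muscle, immediate early and heat shock, and reference gene lists did not pass (adjusted p of 0.0696 to 0.786). Several of these lists were tested on few members: neutrophil on 5 of 13, B cell and plasma cell on 5 of 11, adrenal on 5 of 13 and erythroid cell on 7 of 19. Their results do not show that these cells were unchanged. In the podocyte, endothelium, NRF2, and immediate early lists members went both ways: Cd2ap rose 1.78-fold while Clic5 fell 2.24-fold, Sox18 rose 1.64-fold while Kdr fell 2.38-fold, Hmox1 rose 2.85-fold while Me1 fell 2.38-fold, and Hspb1 rose 9.15-fold while Nr4a1 fell 7.57-fold. For endothelium the mean was -0.03 where the median (0.02) and the test were positive, and for NRF2 targets the median was -0.11 where the mean (0.09) and the test were positive. Among reference genes B2m rose 1.90-fold and Sdha fell 3.01-fold.

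The second comparison asked how far the kidney was from control 12 days after release. The proximal tubule list stood close to its control level, with a median of -0.19 after -1.56 at the end of obstruction. The tubular injury, collagen and macrophage lists stayed higher, with 4 of 23, 6 of 29 and 10 of 23 members past the threshold (camera; adjusted p = 0.123 for each with an estimated correlation). Umod (0.14 ± 0.12), Kap (0.08 ± 0.21) and Slc34a1 (-0.28 ± 0.18, adjusted p = 0.387) did not differ past the threshold (n = 3 per arm, limma, BH-adjusted). Havcr1 was still 4.92-fold higher (2.30 ± 0.36, adjusted p = 0.0333), Col3a1 2.54-fold (1.34 ± 0.25, adjusted p = 0.043) and Ccl2 3.80-fold (1.93 ± 0.24, adjusted p = 0.0212). Arntl, which encodes the clock activator BMAL1, was 5.93-fold higher (2.57 ± 0.27, adjusted p = 0.0204), and Per1, Per2, Dbp and Ciart, which it drives, were lower. With normexp Havcr1 (0.95, adjusted p = 0.161), Col3a1 (1.33, 0.153), Ccl2 (1.20, 0.132) and Arntl (1.34, 0.132) did not pass. The Havcr1 call was also lost with replicate as a block (adjusted p = 0.0644) and without sham 1 (0.0759), sham 2 (0.0787), clip 1 (0.0579), clip 2 (0.0536), release 2 (0.129) or release 3 (0.0848), and that of Arntl without sham 2 (0.0526) or release 2 (0.0758). Col3a1 was lost with quantile normalization (adjusted p = 0.0553), with replicate as a block (0.07) and without any 1 array other than the untreated one (0.0552 to 0.119). Ccl2 was lost without sham 1 (0.0517), sham 2 (0.0623), release 2 (0.0758) or release 3 (0.0597).

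Of the 17742 genes, 259 were higher and 66 lower in release than in control kidneys (limma, BH-adjusted), with 3811 at an unadjusted p under 0.05; 90 and 27 changed 2-fold or more. The arms were apart in all 325 called genes and in 27.2% of all genes, where chance gives 10%. These counts were not firm. They were 751 and 412 with slide as a block, 159 and 43 with the replicate number as a block, 87 and 30 with quantile normalization, 0 and 1 with normexp (1343 unadjusted) and 0 and 0 with the clip arrays left out of the fit (3384 unadjusted). Leaving out 1 array gave 2 and 0 genes without release 2, 10 and 6 without sham 2, 37 and 13 without release 3, 47 and 11 without sham 1, 59 and 14 without clip 1, 92 and 21 without clip 2, 112 and 62 without release 1, and 170 and 42 without clip 3. Each of the 40 named calls was lost under at least 1 of the alternatives run for genes: 39 with normexp, 24 with replicate as a block, 15 with quantile normalization, 8 with the sham arrays alone as the control, 3 with the mean of a gene's probes, 2 with slide as a block, and 8 to 39 on leaving out 1 array. Of the 259 higher genes, 14 were not well above background on any array of either arm.

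The largest rises after release included Sprr2f (at least 3.46-fold), the thyroid hormone activating enzyme Dio2 (at least 5.42-fold), the developmental signal Wnt4 (5.80-fold, 2.54 ± 0.32) and Cav3 (3.85-fold, 1.95 ± 0.25). Pglyrp2 (at least 2.19-fold), Alx1 (3.97-fold) and Ccl12 (at least 2.85-fold) completed them with Arntl, Havcr1 and Ccl2. Of the control arrays, 1 of 3 was well above background for Wnt4 and Havcr1 and 2 of 3 for Cav3, and of the release arrays 1 of 3 for Ciart and Ubxn10. The falls were led by Ciart and included the clock genes Per1, Per2 and Dbp. Ciart fell 8.21-fold (-3.04 ± 0.38), Noct 5.36-fold (-2.42 ± 0.24), Per1 2.89-fold (-1.53 ± 0.20), Per2 2.83-fold (-1.50 ± 0.27) and Dbp 2.75-fold (-1.46 ± 0.17). The glucocorticoid-induced Fkbp5 fell 4.25-fold (-2.09 ± 0.40, adjusted p = 0.0451), Plk3 4.29-fold, Slc25a25 2.74-fold and Kcnk5 2.59-fold. Ubxn10 fell 4.12-fold (adjusted p = 0.0476), a call not kept with slide as a block (adjusted p = 0.0541). Lcn2 did not pass (1.84 ± 0.38, adjusted p = 0.0544; 0.049 with slide as a block). With normexp Noct alone of these genes passed (-2.38, adjusted p = 0.0152), and the log2 changes of Sprr2f, Dio2, Wnt4, Cav3 and Ciart were 0.86, 1.12, 0.94, 0.83 and -1.09. Without release 2 all but Ccl12 of the called genes in this paragraph were lost (adjusted p of 0.0758 to 0.16), and without sham 2 all but Ccl12 and Noct (0.0526 to 0.104). Fkbp5, Plk3 and Ubxn10 were lost with quantile normalization (adjusted p = 0.0586, 0.0604 and 0.0546), with replicate as a block (0.0545, 0.0629 and 0.0646) and with the sham arrays alone as the control (0.0604, 0.0646 and 0.0641). Quantile normalization also lost Per2 (0.0516) and Slc25a25 (0.0586), and replicate as a block lost Dio2 and Pglyrp2 (0.0505 each), Per2 (0.0589) and Kcnk5 (0.0706). With the mean of a gene's probes Fkbp5 (0.0826) and Per2 (0.0562) were lost.

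**Figure D2:**
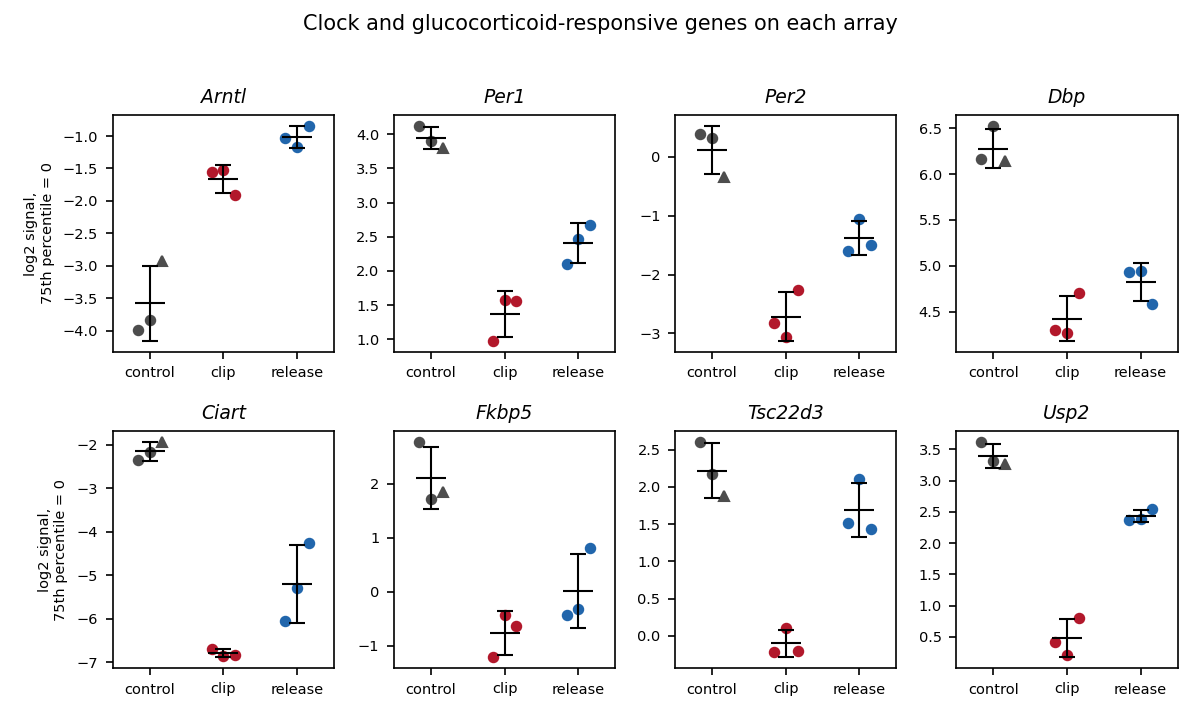
Log2 signal, scaled so that the 75th percentile of each array is 0, of 8 clock and glucocorticoid-responsive genes on each of the 9 arrays, with the mean and SD of each arm as bars; the triangle marks the untreated kidney, and Usp2 and Tsc22d3 were added after the values were seen. Arntl lies 1.92 (clip) and 2.57 (release) above the control arm, and Per1 lies lower in both arms (-2.57 and -1.53).

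The macrophage and collagen lists had the smallest camera p values after release. In the macrophage and monocyte list 10 of 23 members were higher (16 adjusted over the list alone), with a median change of 0.83 (camera, adjusted p = 1.19e-12; adjusted p = 0.123 with an estimated correlation). Lyz1 was 2.75-fold higher (1.46 ± 0.28) and Ccr2, well above background on 2 of 3 release arrays, at least 1.42-fold. In the collagen and matrix list 6 of 29 were higher (23 adjusted over the list alone; median 0.64, adjusted p = 1.06e-13; adjusted p = 0.123 with an estimated correlation). Col1a1 was 2.40-fold higher (1.27 ± 0.25, adjusted p = 0.0488), and Tnc 2.58-fold (adjusted p = 0.0494; 0.0559 with slide as a block). Interstitial fibroblast and pericyte genes were higher as a list (2 of 16 passed, 5 adjusted over the list alone; median 0.46, adjusted p = 1.21e-05; adjusted p = 0.131 with an estimated correlation), with Pdgfrb at 1.83-fold and Pdgfra at 1.80-fold. In the tubular injury list 4 of 23 were higher (14 rose and 1 fell adjusted over the list alone; median 0.53, adjusted p = 2.27e-07; adjusted p = 0.123 with an estimated correlation), Krt20 among them at 2.85-fold. Timp1 (3.43-fold) and Mmp3 (3.65-fold) were higher in the protease list, which passed (adjusted p = 0.0334; adjusted p = 0.502 with an estimated correlation) but not with slide or replicate as a block (adjusted p = 0.0615 and 0.122), without the filter on dim probes (0.224), without sham 2 (0.112) or without release 3 (0.114). Vim was 1.72-fold higher in the myofibroblast list (adjusted p = 0.0135; adjusted p = 0.582 with an estimated correlation; 0.135 without the untreated array and 0.108 without the filter on dim probes), while Acta2 (0.32 ± 0.20) and Tgfb1 (0.24 ± 0.18) did not pass. Krt20 and Mmp3 were well above background on 1 of 3 control arrays. The 10 genes called in this paragraph were all lost with normexp (adjusted p of 0.161 to 0.953; Pdgfrb 0.168 and Pdgfra 0.218) and without sham 2 (0.0526 to 0.111), release 2 (0.114 to 0.149) or release 3 (0.0683 to 0.114). With replicate as a block 9 of them, all but Vim, were lost (0.0526 to 0.0847; Pdgfrb 0.066 and Pdgfra 0.0606), and with quantile normalization Lyz1, Col1a1, Tnc, Krt20, Timp1 and Mmp3 (0.0546 to 0.0668).

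Immune lists stayed above control with few single genes past the threshold. Chemokines (2 of 21 higher; adjusted p = 0.000116), complement (2 of 15, C3 by 3.47-fold and C1s1 by 1.85-fold; adjusted p = 0.00149) and NF-kappaB targets (2 of 21, Il1b by 3.20-fold and Tnfaip2 by 1.89-fold; adjusted p = 0.0129) were higher, with adjusted p = 0.206, 0.123 and 0.53 with an estimated correlation. The NF-kappaB list was lost without the filter on dim probes (adjusted p = 0.0898). Adjusted over the list alone, 3, 8 and 5 of their members rose. The interferon list (adjusted p = 1.44e-06), MHC class II (0.000642) and T and NK cells (0.000165, with Cd3g at least 1.55-fold higher and well above background on 2 of 3 release arrays) followed, with 0, 0 and 1 members past the threshold and 5, 1 and 7 adjusted over the list alone. For these, adjusted p = 0.206, 0.502 and 0.502 with an estimated correlation. The calls of C3, C1s1, Il1b, Tnfaip2 and Cd3g were lost with normexp and without sham 2 (adjusted p of 0.0614 to 0.104) or release 2 (0.0775 to 0.131), and all but Tnfaip2 with replicate as a block (0.0505 to 0.0708). Cd3g was also lost with quantile normalization (0.0707), and C1s1 with the sham arrays alone as the control (0.0549). Gbp3 (0.60 ± 0.13, adjusted p = 0.0576) and H2-Ab1 (0.61 ± 0.14, adjusted p = 0.0614) did not pass, but did with slide as a block (adjusted p = 0.0347 and 0.0473). Endothelium (median 0.16, adjusted p = 0.0156) and urothelium (median 0.31, adjusted p = 0.0272) were higher, with adjusted p = 0.582 and 0.53 with an estimated correlation, and urothelium not with slide or replicate as a block (adjusted p = 0.0502 and 0.135) or quantile normalization (adjusted p = 0.0915). Without the untreated array the urothelium mean fell from 0.57 to 0.26 (adjusted p = 0.329) and that of endothelium from 0.20 to 0.13 (0.121), and endothelium was also lost without release 2 (0.0894). Without the filter on dim probes neither list passed (adjusted p = 0.116 for each).

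Tubule lists stood within 0.4 log2 units of control, which is a range set after the values were seen. The proximal tubule list was slightly lower (median -0.19, none of 31 past the threshold; adjusted p = 0.0156; adjusted p = 0.616 with an estimated correlation), but not with quantile normalization (adjusted p = 0.344) or without release 3 (0.0728). The thick limb and distal tubule (median 0.16, adjusted p = 0.0205) and principal cell lists (median 0.32, adjusted p = 0.0209) were slightly higher, with adjusted p = 0.444 and 0.53 with an estimated correlation. The first was lost without release 3 (0.0771) or without the filter on dim probes (0.16), and the second without sham 2 (0.0809), without release 1 (0.0647) or without this filter (0.113). In these the magnesium channel Trpm6 rose 1.72-fold (adjusted p = 0.0452) and Elf5 did not pass (0.96 ± 0.25, adjusted p = 0.083; 0.0484 with slide as a block). Trpm6 was lost with normexp (adjusted p = 0.932), with quantile normalization (0.0586), with the sham arrays alone as the control (0.0576) and on leaving out any 1 array (0.0549 to 0.159). Fatty acid oxidation (median -0.16, adjusted p = 0.00229), gluconeogenesis (-0.24, 0.0135), xenobiotic metabolism (-0.18, 0.0402) and the respiratory chain (-0.13, 0.0393) were lower by the preset test only: adjusted p = 0.582, 0.582, 0.582 and 0.694 with an estimated correlation. With quantile normalization their adjusted p were 0.0957, 0.0957, 0.344 and 0.595, the mean of the respiratory chain was 0.05, and xenobiotic metabolism was also lost with slide as a block (adjusted p = 0.0851). Immediate early genes (adjusted p = 0.0469) and reference genes (0.0393) were lower as lists, with adjusted p = 0.582 and 0.53 with an estimated correlation, and 0.202 and 0.414 with quantile normalization. For immediate early genes adjusted p = 0.13 with slide as a block. Xenobiotic, respiratory chain and reference genes were lost with normexp (adjusted p = 0.0716, 0.379 and 0.241) and with replicate as a block (0.0634, 0.18 and 0.168). Xenobiotic, respiratory chain, immediate early and reference genes were lost without sham 1 (adjusted p of 0.119 to 0.232), sham 2 (0.0949 to 0.155) or release 3 (0.123 to 0.254). The last 3 were lost without release 2 (0.0509 to 0.0975), and immediate early genes without clip 3 (0.0625) or release 1 (0.0527). The cell cycle list was not different (median -0.01, mean 0.03, adjusted p = 0.631), although Tk1 fell 1.61-fold. The other 14 lists did not pass (adjusted p of 0.133 to 0.986). Among them Cbr3, an NRF2 target, was 1.74-fold higher and Casp12 1.86-fold. Tk1, Cbr3 and Casp12 were lost with normexp (adjusted p = 0.264, 0.175 and 0.95) and without sham 1, sham 2, release 2 or release 3 (0.0517 to 0.139), Tk1 and Casp12 with replicate as a block (0.0505 and 0.0775), and Casp12 with quantile normalization (0.0594). The test of the NRF2 list and its median (-0.05) were negative where the mean (0.04) was positive, and the p53 list had a median of -0.06 where the mean (0.03) and the test were positive. The renin-angiotensin list had a median of -0.03 where the mean (0.05) and the test were positive.

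**Figure D3:**
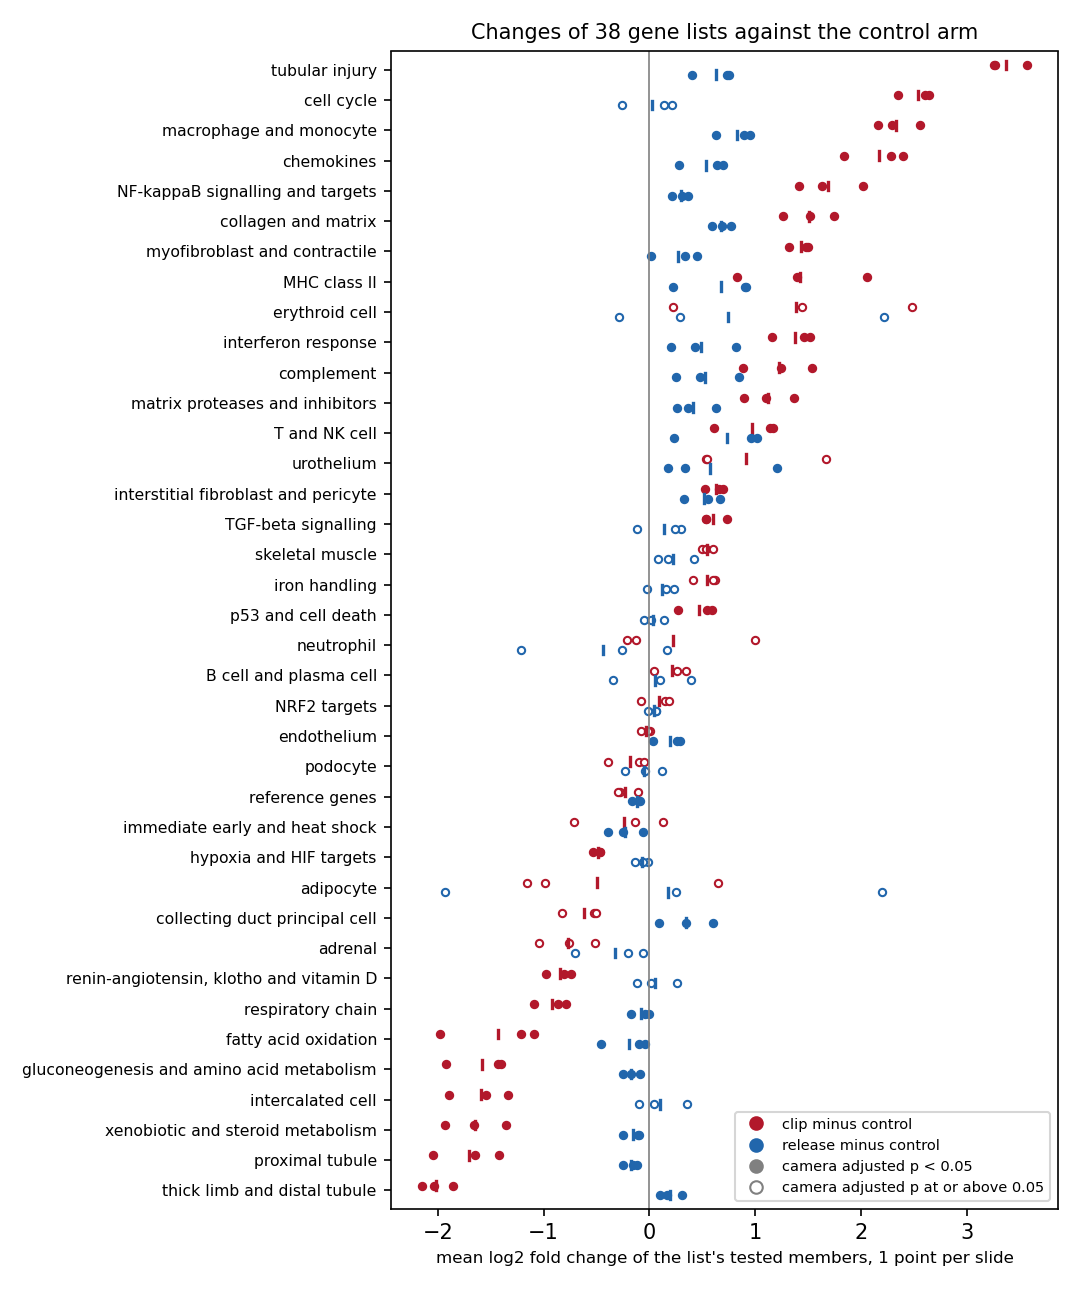
Mean log2 fold change of the tested members of each of the 38 lists on each of the 3 slides, clip minus control and release minus control, with a vertical tick at the mean over slides; filled points mark lists with camera adjusted p under 0.05 at the preset correlation. By the mean over slides, tubular injury and cell cycle genes lie highest at the end of obstruction. On slide 2 macrophage genes (2.55) lie above cell cycle genes (2.35). After release 23 lists passed, 0 of them with an estimated correlation.

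The third comparison set the released against the obstructed kidneys directly. Release reversed both sides of the response: Egf rose 106-fold (6.73 ± 0.10, n = 3 per arm; limma, BH-adjusted p = 2.56e-08), and Havcr1 fell 149-fold (-7.22 ± 0.36). Lcn2 fell 32.6-fold (-5.03 ± 0.38), Acta2 5.57-fold (-2.48 ± 0.20) and Col1a1 4.19-fold (-2.07 ± 0.25). Slc34a1 rose 4.15-fold (2.05 ± 0.18), Umod 1.90-fold and Kap 1.71-fold; the call of Kap was lost without clip 3 (adjusted p = 0.0549) or release 1 (0.0511). Pdgfrb was the exception among the stromal genes named throughout and did not pass (-0.43 ± 0.15, adjusted p = 0.0507; 0.0269 with quantile normalization).

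There were 4178 genes higher and 3092 lower in release than in clip kidneys (limma, BH-adjusted), 1345 and 1156 of them by 2-fold or more. Arms did not overlap in 7209 of these 7270 genes and in 54.8% of all genes, where chance gives 10%. With quantile normalization the larger side changed here too, with 3644 higher and 3718 lower. With normexp 2270 were higher and 1874 lower, and 836 of the 7270 had the other sign; without the filter on dim probes 10515 were higher and 3082 lower. The median level of the 14964 probes that were above background on no array differed between the arms by 0.55 on the log2 scale.

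Pvalb and Tmem207 rose at least 16.7-fold and 20.7-fold from clip levels not well above background. Ces1g, Ces1e (4.62 ± 0.20), Hpd (4.76 ± 0.30), Gpx6 (4.73 ± 0.21) and the potassium channel Kcnt1 (4.78 ± 0.26) rose 24.6-fold to 32.1-fold. Odf4 rose at least 10.6-fold and Sox2ot at least 9.31-fold, calls that were not kept with normexp. Fgb fell 184-fold (-7.52 ± 0.28), Fgg 61.8-fold (-5.95 ± 0.17), Sprr2f 55.6-fold (-5.80 ± 0.48) and Tmem145 48.6-fold (-5.60 ± 0.34). Timp1 fell 46.0-fold and Serpina10 44.4-fold; Tmem145 and Serpina10 were well above background on 1 of 3 release arrays. Saa2, Il1rn and Ccl20 fell at least 34.5-fold, 13.3-fold and 9.52-fold to levels not well above background. With normexp the changes of genes dim in 1 arm were again smaller, among them Pvalb (1.53), Tmem207 (1.64), Il1rn (-2.27) and Ccl20 (-2.27), all past the threshold. Changes given as plain folds were smaller too, among them Ces1g (3.07), Hpd (2.84), Kcnt1 (2.77), Tmem145 (-3.34) and Serpina10 (-3.14). Fgg (-5.51) and Ces1e (4.05) moved less.

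Recovery of nephron genes was broad. In the proximal tubule list 28 of 31 rose and 1 fell (29 and 1 adjusted over the list alone; median 1.28, adjusted p = 2.47e-10; adjusted p = 0.185 with an estimated correlation), with Slc7a13 up 16.5-fold, Mep1b 12.2-fold, and Slc13a1 down 2.29-fold. In the thick limb and distal tubule list 18 of 20 rose and Trpv5, well above background on 2 of 3 release arrays, fell 2.74-fold (median 1.86, adjusted p = 1.45e-10), and this call held with an estimated correlation (adjusted p = 0.0283). Slc4a1 rose 22.4-fold and Insrr 5.84-fold in the intercalated cell list (13 of 15 rose; adjusted p = 4.84e-07; adjusted p = 0.162 with an estimated correlation); Insrr did not pass with normexp. Principal cell genes were higher as a list (9 of 12 rose, Aqp3 by 5.27-fold and Aqp2 by 3.92-fold; adjusted p = 0.00136; adjusted p = 0.185 with an estimated correlation). All 31 respiratory chain genes rose, Sdha by 2.71-fold (median 0.79, adjusted p = 1.45e-10; adjusted p = 0.185 with an estimated correlation). The fatty acid oxidation (25 of 30, 26 adjusted over the list alone), gluconeogenesis (22 of 25), xenobiotic (25 of 28, 26 adjusted over the list alone), hypoxia (15 of 25, 16 adjusted over the list alone) and renin-angiotensin lists (8 of 12) were higher, with adjusted p of 1.01e-09, 3.79e-08, 8.56e-10, 0.00311 and 0.0067. For these 5, adjusted p = 0.185, 0.185, 0.151, 0.0907 and 0.177 with an estimated correlation. G6pc rose 10.6-fold, Cyp2d12 8.52-fold, Car9 8.27-fold, Ren2 5.05-fold and Kl 3.73-fold.

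Proliferation and injury genes fell most. In the cell cycle list 29 of 31 fell (median -2.53, adjusted p = 2.13e-21), with Top2a at least 9.41-fold and Aurkb at least 4.14-fold lower and both not well above background after release. All but 1 of the 23 tubular injury genes fell (median -1.86, adjusted p = 8.56e-16). Both calls held with an estimated correlation (adjusted p = 0.0283 each). Macrophage genes (20 of 23 fell, 21 adjusted over the list alone, Chil3 by 18.6-fold; median -1.46, adjusted p = 1.45e-10), chemokines (15 of 21, Ccl7 at least 4.34-fold; adjusted p = 2.24e-07) and NF-kappaB targets (15 of 21, Tnfrsf12a by 7.34-fold; adjusted p = 1.65e-08) were lower, with adjusted p = 0.0907, 0.101 and 0.151 with an estimated correlation. Cxcl12 rose 4.72-fold against its list. The myofibroblast (12 of 16 fell, Actn1 by 4.12-fold), collagen (19 of 29 fell, 21 adjusted over the list alone, Col8a1 by 5.66-fold and Col3a1 by 4.46-fold), protease (12 of 21) and TGF-beta lists (12 of 26, Tgfbi by 5.23-fold) were lower, with adjusted p of 7.89e-08, 1.3e-07, 0.0106 and 0.00888; adjusted p = 0.185, 0.165, 0.185 and 0.214 with an estimated correlation. Col6a1 rose 2.02-fold within the collagen list. Interferon (18 of 23 fell, 19 adjusted over the list alone, Gbp2 by 4.13-fold), MHC class II (4 of 9) and p53 genes (8 of 21, Ripk3 by 5.36-fold) were lower, with adjusted p of 4.87e-08, 0.0191 and 0.00719; adjusted p = 0.146, 0.468 and 0.162 with an estimated correlation. The p53 list was lost with normexp (adjusted p = 0.0576) and MHC class II without clip 2 (mean -0.49 in place of -0.75, adjusted p = 0.1). The remaining 16 lists did not pass (adjusted p of 0.118 to 0.827), among them interstitial fibroblasts and pericytes, where Thy1 fell 3.94-fold and Rgs5 rose 2.46-fold, and complement, where C3 fell 23.7-fold and Cd55 rose 2.30-fold. Median and mean differed in sign for NRF2 targets (0.08 against -0.05), for reference genes (-0.01 against 0.11, the test negative), and the test was negative for immediate early genes with a median of 0.23 and a mean of 0.01.

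Both comparisons with control used the same control arrays, which by itself makes their changes alike. The changes correlated at 0.513 across genes, against 0.501 in simulated unchanged groups with a shared control, with a covariance of 0.201 against 0.0269. Genes are not independent replicates here. Of the 259 genes higher after release, 231 were also higher at the end of obstruction, and of the 66 lower genes 51 were shared. Simulated unchanged groups shared 0, which leaves out the effects, and independent lists would share 55.3 and 18.2, which leaves out the shared control; part of the excess may come from the shared control arrays, and no shared effect is read from it. The slope of the release change on the clip change across genes was 0.194 with the shared-control part removed, and 0.185 (0.145 to 0.217) when the changes were taken from different slides, which share no array. Of the genes higher at the end of obstruction, 71.3% were lower again in release minus clip, and of the lower genes 72.7% were higher again. These 2 comparisons share the clip arrays with opposite sign. Part of the return follows from this alone, and no value for unchanged groups was computed. Among those changed 2-fold or more, the median share of the change left after release was 24.8% (quartiles 9.19% to 40.0%) for rises and 14.8% (2.05% to 28.2%) for falls. It was 20.7% and 12.1% with quantile normalization, and with normexp the order turned (12.9% and 16.2%). The numbers shared were not firm either: they were 0 and 1 with normexp, 82 and 20 with quantile normalization, and 615 and 336 with slide as a block. Leaving out 1 array gave 2 and 0 without release 2, 8 and 3 without sham 2, 34 and 8 without release 3, 46 and 9 without sham 1, 54 and 7 without clip 1, 81 and 16 without clip 2, 98 higher without release 1, and 150 and 32 without clip 3.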

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

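The genes in this part and the tests of the clock genes and of a lower tubule share were chosen after the values were seen; the tests of array scaling and of the shares kept were set before, except that of normexp among genes above background on all 9 arrays. In 11 genes the change against control was called in opposite directions at the end of obstruction and after release (limma, BH-adjusted). They were 6 lower then higher genes and 5 higher then lower genes. Among the 6, with log2 changes given for clip and then release, were Syt13 (-0.97 and 0.86), the magnesium channel Trpm6 (-0.52 and 0.78) and Aire (-2.00 and 0.95), with 3 transcripts known by accession alone. The 5 were the proliferation genes Tk1 (1.36 and -0.69), Stmn1 (0.80 and -0.86) and Oip5, the folate enzyme gene Mthfd1l (1.11 and -0.81), and Ranbp17, where Oip5 and Ranbp17 were not well above background after release. With normexp none of the 11 passed after release.

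The first pattern is the clock. Of 11 tested genes that peak with the evening phase, 11 fell at the end of obstruction and 6 after release, and none rose. Kidneys taken at different times of day would move clock genes not named by the rule as a shift of phase asks, and 8 of 9 had that sign after release, of which 2 passed; the files do not give the time of collection, so this explanation stays open. Slide or scan batch is argued against, since each slide held 1 array of each arm and 7 of the 9 genes not named by the rule had the sign of a shift of phase on each of the 3 slides. After release, a loss of tubule cells is argued against as the whole cause. The median of the 7 evening genes not named by the rule then lay below that of the proximal tubule list on each slide. The gap was at the closest -0.29, just beyond the largest difference of either median between slides (0.27). This test covered release only. At the end of obstruction the slide medians of the proximal tubule list were -1.96 to -1.23. All 11 evening genes had a median of -1.85 at that time. A loss of tubule cells therefore stays open there. An effect of obstruction on the clock itself also stays open and was not tested.

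The second pattern is the fall of tubule genes with the rise of immune and matrix genes at the end of obstruction. A lower share of tubule RNA alone would raise all other cell types alike. On the slide where they were closest, the macrophage list's median lay 1.98 log2 units above the higher of the podocyte and endothelium medians, more than any of these lists differed between slides, which argues against it as the whole cause. Array scaling is argued against because the smallest median fall of the proximal tubule list over the 3 scalings was -1.31, where scaling moved the median of all genes by at most 0.19. A change of expression within the tubule cells, an influx of immune cells, or both, as effects of obstruction, may account for the pattern and were not told apart by the 1.98 units.

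The third pattern is that genes induced by obstruction kept a larger share of their change after release than repressed genes (24.8% against 14.8%). Dim genes alone are argued against as the cause, since the difference was 8.65 percentage points among genes above background on all 9 arrays. The shared control arrays are argued against only in part: the induced genes kept more in 6 of 6 pairs of different slides. The genes and their direction were still chosen from all arrays, and the 6 pairs reuse the same 3 slides. Array scaling stays open: with normexp the difference was -3.32 points, so that the order turned, and with quantile normalization it was 8.56. With normexp among genes above background on all 9 arrays it was 2.91, so the background treatment of the signals may account for much of the pattern.

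The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Each split but the real one joins 2 arrays of an arm with 1 of the other arm. The difference between the arms then enters the spread, so few calls follow by construction. The counts of these splits are no measure of chance. In clip minus control the real split called 8676 genes and the highest of the others 2, also among the 4 splits that part every slide. In release minus control the real split called 325 and the highest of the others 2, or 0 among those that part every slide. In release minus clip the numbers were 7270 and 1, or 0 among those that part every slide. In each comparison 1 of the 10 splits, the real one, gave as many genes.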

How the results depend on the processing

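The fits without slide 3, the blocked counts of shared genes, the slide block for lists, named genes and untreated minus sham, and the shares kept by single lists under each scaling were chosen after the data were seen. With quantile normalization the larger side of the counts changed, to 4353 higher and 4210 lower in clip minus control and to 3644 higher and 3718 lower in release minus clip. With normexp background correction the genes higher and lower were 2519 and 3107 in clip minus control, 2270 and 1874 in release minus clip, and 0 and 1 in release minus control, with 0 and 1 shared with obstruction. The number differing between untreated and sham kidneys fell from 93 to 0 with normexp (574 at an unadjusted p under 0.05) and was 97 with quantile normalization and 31 with slide as a block. With a 2-fold threshold the counts were 1674 and 1684, 90 and 27, and 1345 and 1156, fewer by construction. Without the filter on dim probes release minus clip gave 10515 higher genes, where the probes above background on no array differed between the arms by 0.55 log2 units. Release minus control then gave 11 and 1, with 9 and 1 shared.

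Release minus control moved under most settings: 87 and 30 with quantile normalization (82 and 20 shared), 122 lower (101 shared) with only probes above background on all arrays, 160 lower with a trended and robust prior, 0 and 0 with only the arms compared (3384 unadjusted), 751 and 412 with slide as a block (615 and 336 shared), 721 and 313 with scan date as a batch, 159 and 43 with replicate as a block (143 higher shared), and 2 and 0 without the arrays of slide 3, which is also the loss of 3 arrays. The share of the calls that were higher was 79.7%, against 64.6% with slide as a block and 91.7% without the filter; the cause was not tested.

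Leaving out 1 array gave 3159 to 3738 higher and 3988 to 4867 lower genes in clip minus control, 3253 to 4391 and 2459 to 3261 in release minus clip, and 2 to 264 and 0 to 79 in release minus control, with 2 to 226 and 0 to 59 shared. The lowest release counts came without release 2 and the highest without untreated 1.

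Lists were run with normexp, quantile normalization, no filter, sham arrays alone, slide and replicate as blocks and each array left out. These kept the calls of 22 of 24 lists in clip minus control, 20 of 22 in release minus clip and 9 of 23 in release minus control. Those 9 were fibroblasts and pericytes, collagen, chemokines, macrophages, T and NK cells, tubular injury, interferon, complement and MHC class II. These counts leave out the estimated correlation, with which 0 of 24, 3 of 22 and 0 of 23 calls held. The 9 lists kept in release minus control then had camera adjusted p of 0.123 to 0.502. A higher correlation between genes does not account for all of this loss. In clip minus control the estimated correlations of the hypoxia and complement lists were -0.00283 and -0.0218, below the preset 0.01. Their camera p still rose, from 0.00076 to 0.00951 and from 0.00306 to 0.0195. Some lists that did not pass in the main fit passed under an alternative. In clip minus control there were 3 such results with normexp, 1 without the filter and 5 over the fits leaving out 1 array. In release minus control there was 1 without the filter, 1 with replicate as a block and 4 on leaving out 1 array. In release minus clip there were 3 with normexp and 5 without the filter. The mean of the respiratory chain list in release minus control turned from -0.0754 to 0.0547 with quantile normalization. Of the named results past the threshold, 100 of 124 in clip minus control, 96 of 124 in release minus clip and 0 of 40 in release minus control kept their call and sign under the same alternatives, with the mean of a gene's probes in place of no filter. With normexp the sign turned in clip minus control for Angpt1 (0.35), Klf1 (0.10) and Actn3 (0.47), and in release minus clip for Angpt1 (-0.45), Mmp13 (-0.12), Ltbp1 (-0.11), Heph (-0.11), Klf1 (-0.0772), Actn3 (-0.29) and Pygm (-0.44); the cause was not tested. With slide as a block Ubxn10 and Tnc were lost in release minus control, while Lcn2, Elf5, Gbp3, H2-Ab1, Esam, Sox18, Ppara, Stat2, Casp1, Ifng, B2m and others then passed. Il1b was lost and Ltf passed in release minus clip, and Csf3r passed in clip minus control. The deposited value table was not run as an alternative, since its names and values do not match. Signals near background limit the folds of genes above background in a single arm. These are given as "at least" folds, which are not strict bounds, since normexp gave smaller changes for several of them.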

Other observations

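The lists and gene families in this part were chosen or compared after the data were seen. The share of its change that a list kept after release is the ratio of the mean changes of release and clip against control. As a list, interstitial fibroblast and pericyte genes, of which 2 of 16 passed after release, kept 82.3% of the mean change. The range was 47.2% to 105% over pairs of different slides, with 68.2% with normexp and 72.8% with quantile normalization. Members of this list moved both ways: 8 rose and 2 fell at the end of obstruction, and 3 rose and 4 fell in release minus clip. Its ratio of means is therefore not the share that single genes kept. Collagen and matrix genes kept 45.2% (33.8% to 61.5%; 43.1% and 42.9%) and macrophage genes 35.5% (24.9% to 44.2%; 30.3% and 32.4%). Tubular injury genes kept 18.7% (11.3% to 23.1%; 12.9% and 18.0%) and cell cycle genes 1.16% (-9.90% to 8.99%; -4.61% and -1.17%). T and NK cell genes moved with the processing, from 75.8% (19.8% to 165%) to 27.7% with normexp. Proximal tubule genes kept 10.2% of their fall (5.69% to 17.5%; 8.85% and 3.96%), and the mean of thick limb and distal tubule genes had the other sign after release (-9.71%, -15.3% to -4.84%; -10.5% and -13.3%), where 1 of 20 genes passed and adjusted p = 0.444 with an estimated correlation.

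Among 287 tested solute carriers, 156 fell and 38 rose at the end of obstruction (median -0.53), and after release 5 were lower and 2 higher than control. Slc25a24 rose by 2.87 on the log2 scale. Of 48 cytochromes P450, 26 fell and 7 rose (median -1.01), with Cyp4f15 lower and not well above background at that time, and Cyp2r1 at 2.03 from a level well above background on 1 of 3 control arrays, and none passed after release by limma. Among 15 keratins 10 rose and 1 fell (median 1.16): Krt20 rose by 6.07, also from 1 such array of 3, and Krt10 fell by 1.52. In the released kidneys 2 keratins were still higher. Claudins split, with 7 of 17 higher, led by Cldn1 (2.43), and 4 lower, led by Cldn10 (-1.28). Of 74 ribosomal protein genes 31 rose, 1 fell and 42 did not pass (camera, p = 1.84e-07; p = 0.305 with an estimated correlation), with a median of 0.27 that was 0.57 with quantile normalization and 0.07 with normexp. These medians kept their sign under the 3 scalings.

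Other clock genes were looked at beside those the rule named. At the end of obstruction Usp2 fell by 2.92 (SE 0.16), Hlf by 2.64, Per3 by 1.84, Tef by 1.81 and Cry2 by 1.30 on the log2 scale, and Nr1d1 and Nr1d2 fell by 0.69 and 1.01. After release Usp2 (-0.97) and Cry2 (-0.71) passed and the other 5 did not; with normexp neither passed. Of 8 tested glucocorticoid-responsive genes, 5 fell and 1 rose at the end of obstruction: Tsc22d3 fell by 2.32, Sgk1 by 1.74, Klf9 by 1.66, and Mt2 rose by 1.20. After release 2 of the 8 were lower, Fkbp5 and Klf9 (-0.72, limma adjusted p = 0.0487). Both calls were lost with normexp.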
